A study of Mus musculus with 4 samples.

How the data were processed

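Gene expression was measured in 4 samples of sorted mouse 4T1 cells, 1 array for each combination of ALDH arm (low or high) and zeitgeber time (ZT0 or ZT12), as the labels give them. Per the labels, total RNA was isolated with a column kit, amplified and labelled with Cy3 with a low-input labelling kit, and hybridised to one-colour arrays. Per the file headers, the scans were read by Agilent Feature Extraction 10.7.1.1 on an array design whose grid names genome build mm9; the submitters' processing notes give version 9.5.1.1 of the same software, and which applies to the deposited values is not known. Per the file headers, the processed signal is an intensity on a linear scale, background-subtracted and detrended within each array, with surrogate values for spots not above background, and not normalized between arrays. The deposited spot means, background medians and flags (well above background, saturated, outlier) were used beside it. The deposited series table of the authors also holds intensity values on a linear scale. Its 4 columns each have a median of 28.3, their sorted values agree within 0.0517%, and each has a rank correlation of 1 with the processed signal of its own array, so the table is quantile normalized and uncentred; the software that made it is not given in the sources used here. Every column could be matched to a sample by its name.

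Control spots were left out, as were outlier spots unless every spot of a probe was one. Replicate spots of a probe were averaged on the log2 scale, and the log2 processed signal minus the 75th percentile of the array was used. Of 56605 probes, 34573 were well above background on at least 2 of the 4 arrays. One probe stood for each gene name, that with the highest mean level. Gene names are those of the array design. Of 14630 tested features with a RefSeq accession, 14481 were found in the RefSeq gene table of assembly GRCm38.p6, which was used for names alone, since only 8.98% of probe positions fell inside its gene spans; positions are given in mm9 as in the files, and exon or UTR positions were not analysed here. No sample had a replicate. Precision within an array was high (the median SD of replicate spots was between 0.0370 and 0.0450 log2 units over at least 291 probes), but says nothing about the spread between tumours. The slope of the spike-in controls was 0.873 and 0.789 on the arrays at position 1_1, which the scanner software marked for evaluation, and 0.956 and 0.944 on those at position 1_2. Nothing in the sources used here says how many mice gave each fraction, so the p-values of single genes measure the spread between these 4 arrays alone. Those of gene lists set a list against the spread across genes, and do not measure the spread between tumours.

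Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 23520 features, threshold 0.05) in an additive fit with ALDH arm and time. The variance prior had infinite degrees of freedom, so every gene shares one spread, and a gene would have needed a difference of 7.31 log2 units for the first call. The 36 gene lists, with 765 of their 770 genes on the array (5 of them matched through a synonym), were fixed before the data were examined. They cover ALDH, clock, Wnt, Notch, Hedgehog, stress and metabolic genes, tumour cell states, and markers of other cell types a sorted tumour fraction could hold. Lists of at least 5 measured genes were tested with limma camera at an inter-gene correlation of 0.01, Benjamini-Hochberg over the lists. Beside each, the median difference at each time was ranked among 10000 random lists matched on mean level in 20 bins. A probe that was not well above background on one array of a contrast has a bound only: the brighter array over the higher of the dim probe's own value and the lowest signal among probes well above background on that array. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

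The genes named were chosen by a rule written before the data were examined. It takes genes well above background on all 4 arrays with a symbol that is not a predicted or clone name. For ALDH it takes the 8 highest and 8 lowest by mean difference among those with at least 1 log2 unit in the same direction at both times, and for time the 6 highest and 6 lowest likewise. It adds 14 genes fixed in advance (named with a bound or as not well above background where needed), 3 members of each called list in the direction of the list, 3 ALDH family genes, 3 Wnt ligands, and the 3 highest and 3 lowest values of ALDH by time. Some list members that the rule chose are not used here and were not replaced. In all, 104 genes were named by it, and 5 of the named genes had probes of opposite sign for ALDH: Myh10, Per3, Ptprc, Bax and Bcl2l1.

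The fit was tested on simulated arrays. For the ALDH comparison over 23520 genes with the observed residual spread of 1.54 log2 units, 200 genes were given known changes; the fit recovered 0% of those changed by 2 log2 units, 10.4% of those changed by 4 and 87.9% of those changed by 8, with 4 false calls. With a spread of 0.513 it recovered 73.1% of the changes of 2 log2 units and 100% of the larger ones, with 12 false calls. At that lower spread, with independent noise for each gene, camera called the 3 lists given a shift and 0 others. In 100 further simulated sets there was no ALDH effect. Each array held a random amount of the observed difference between positions, plus noise independent for each gene. On these, camera at a correlation of 0.01 called between 0 and 13 lists with a median of 8. With an estimated correlation it called a median of 0 lists.

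Alternatives fixed before the data were examined were normexp background correction with an offset of 50 and quantile normalization, quantile normalization of the processed signal, median scaling, the background filter on all 4 arrays or none, the mean of a gene's probes, all probes, the deposited series table, no term for the other factor, slide as a block (the same as the time term), an intensity trend with robust eBayes, other inter-gene correlations, and leaving out each array with no term for the other factor. Fits with array position as a block and list tests without 1 array were added after the data were seen. A test between positions, also added then, is not used here, since the pairing of the arrays already seen fixed its outcome. No sample and no table of values was left out.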

Results

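RNA was measured in sorted cells of tumours that 4T1, a mouse mammary carcinoma line, formed in BALB/c mice. The labels name 4T1 cells, but blood cell transcripts such as Hba-a1, Gzma and Ptprc were well above background on all 4 arrays. The fractions may therefore also hold blood cells. The cells had been sorted by the ALDEFLUOR reaction, in which aldehyde dehydrogenase (ALDH) converts a substrate to a fluorescent product, into fractions of low and high ALDH activity. Tumours were taken at zeitgeber times ZT0 (lights on) and ZT12 (lights off). Each of the 4 combinations of time and ALDH arm was hybridised to 1 one-colour Agilent array, so no group had a replicate, and the number of arrays limits the precision of every value. The 75th percentile of the processed signal was 213.6 on the ZT0 ALDH-low array, 300.6 on ZT0 ALDH-high, 458.8 on ZT12 ALDH-low and 156.3 on ZT12 ALDH-high. Between 55.8% and 60.6% of the 59305 non-control spots were well above background, and 0 spots were saturated. After filtering, 23520 genes and other named features were tested, of which 14681 carried a gene symbol that was not a predicted or clone name. Both ZT0 arrays lay on slide 1 and both ZT12 arrays on slide 2, so time and slide cannot be told apart. Position 1_1 of the slides held ZT0 ALDH-low and ZT12 ALDH-high, and position 1_2 held ZT0 ALDH-high and ZT12 ALDH-low.

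The first comparison asked which transcripts differ between cells of high and low ALDH activity, the property used to enrich tumour cells with stem-like behaviour. Among genes that differed in the same direction at both times, the largest mean differences were those of genes with lower signal in the ALDH-high fraction. In this paragraph and the next 2, paired values are the ALDH-high minus ALDH-low log2 difference at ZT0 and then at ZT12. The 8 lowest genes were Ankrd1, a target of YAP signalling (-4.24 and -1.51), Mst1r, the receptor tyrosine kinase RON (-4.23 and -1.02), Steap1 (-4.13 and -1.03), Apcdd1, a Wnt inhibitor (-3.41 and -1.41), Csf3, which encodes G-CSF (-2.89 and -1.56), Myh10 (-3.27 and -1.07), Mmp3, stromelysin-1 (-2.66 and -1.62), and Pitx1 (-3.23 and -1.05). The 8 highest were Smad6, an inhibitory SMAD (2.77 and 1.64), Ggps1 (1.41 and 1.94), Arhgef10 (1.04 and 2.31), the T cell receptor component Cd3d (1.90 and 1.03), the telomerase RNA Terc (1.39 and 1.25), the heat shock genes Hspa1b (1.22 and 1.27) and Hspa1a (1.24 and 1.22), and Olfr223 (1.24 and 1.15). Hspa1a and Hspa1b are near-identical copies whose probes may share targets, so they are uncertain as separate genes. Cd3d ran against most T and NK cell markers, a list tested below, of which 18 of 22 were at least 2-fold lower at ZT0 (median -2.61). One of the 3 Myh10 probes had the opposite sign. The Csf3 probe (A_51_P317176) lies on chromosome 11 at 98564614-98564673 in build mm9, the Ankrd1 probe (A_52_P120803) on chromosome 19 at 36186809-36186868 and the Hspa1a probe (A_52_P82741) on chromosome 17 at 35106766-35106825. None of these differences passed the test. In the additive limma fit 0 genes were called for ALDH at an adjusted p of 0.05, with 7 genes at an unadjusted p under 0.05, and the smallest adjusted p rounded to 1. The fit has 1 residual degree of freedom, which is the ALDH by time difference, and gave every gene a standard error of 1.54 log2 units; the 2 times are not replicates of one condition.

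**Figure D1:**
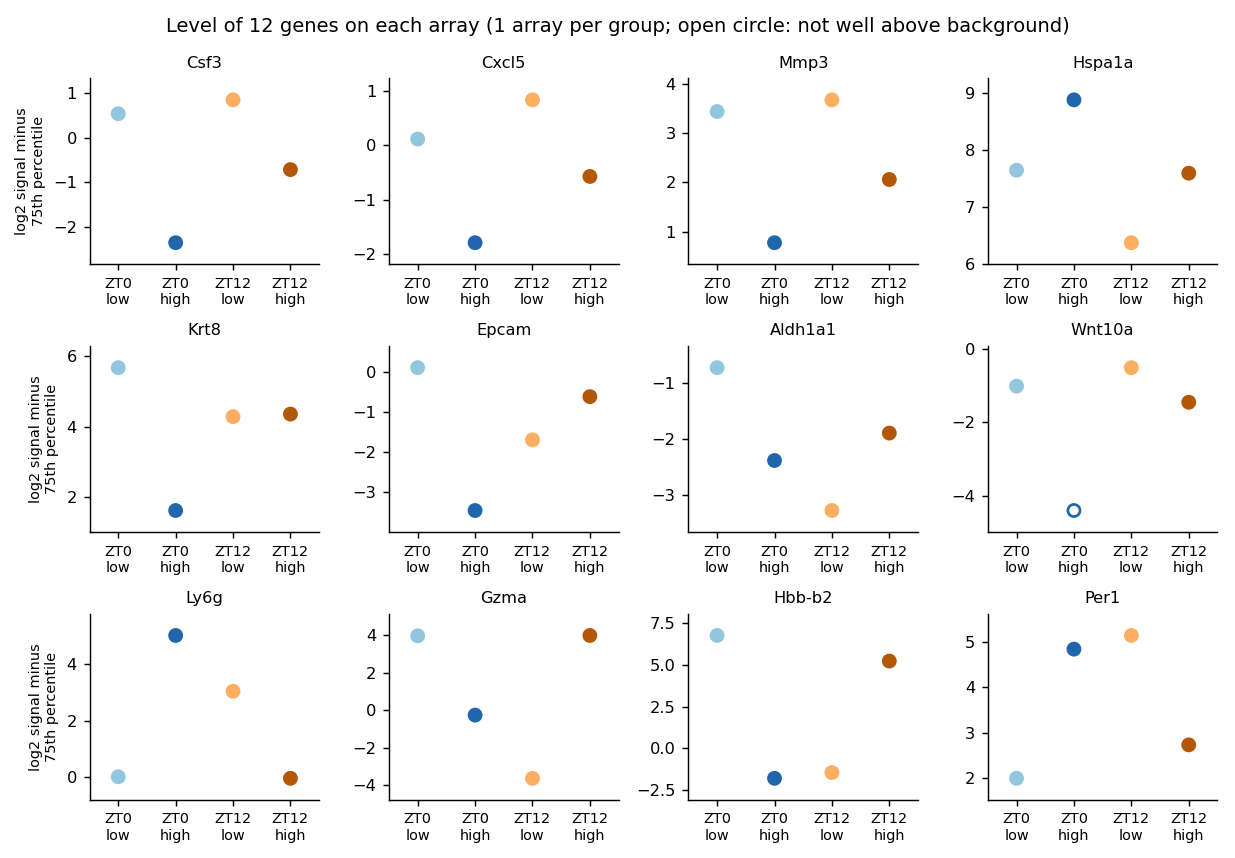
Normalised level (log2 signal minus the 75th percentile of the array) of 12 genes on each of the 4 arrays, 1 point per array, with an open circle where the probe was not well above background. Csf3, Cxcl5 and Mmp3 were lower on the ALDH-high array at both times, while Ly6g, Gzma, Hbb-b2 and Per1 differed in opposite directions at ZT0 and ZT12.

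ALDH genes did not follow the sort in one direction. Aldh1a1, the isoform most often tied to the ALDEFLUOR reaction, was lower in the ALDH-high fraction at ZT0 and higher at ZT12 (-1.65 and 1.38). Aldh3a1 ran the other way (1.04 and -0.68), and its mean of 0.18 changed sign under median scaling, which moves the ALDH mean of every gene by the same amount. Aldh1a3 was well above background on the ZT12 ALDH-low array alone and has no fold. The members with the largest mean difference were Aldh7a1 (-1.92 and 0.06), Aldh1l2 (-1.61 and 2.78) and Aldh1l1 (-2.16 and 1.09). Of 17 measured ALDH family genes, 7 were at least 2-fold higher and 7 at least 2-fold lower at ZT0, 0 passed the test whether adjusted over all genes or adjusted over the list alone, and the list was not called (camera adjusted p = 0.635). Its median and mean were slightly above 0 while the test direction was down. Wnt10a, a Wnt ligand, was at least 10.5-fold lower on the ZT0 ALDH-high array, where it was not well above background, and differed by -0.94 at ZT12. The Wnt ligands with the largest mean difference among those well above background on all arrays were Wnt7b (-3.14 and -0.35), Wnt11 (0.49 and 0.97) and Wnt5a (-0.45 and 1.58), and the 13 measured ligands were not called as a list (adjusted p = 0.178; median 0.23, mean -0.13). Their median was -1.94 at ZT0, at percentile 0.14 of random lists, with 9 ligands at least 2-fold lower and 1 higher, and 0.97 at ZT12, inside the random range. Epcam, the epithelial adhesion molecule, gave -3.57 and 1.08, and Ptprc, the leukocyte antigen CD45, gave 3.09 and -2.35; one of its 7 probes had the opposite sign of the mean difference.

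Gene lists fixed before the data were examined were compared with all other genes at a preset inter-gene correlation of 0.01. For ALDH, 15 were called. In the simulated sets with no ALDH effect, camera called a median of 8 lists and at most 13 at this correlation. The count of 15 lies above that range. The simulated noise was independent for each gene, so genes of a list varied together only along the difference between positions. The range may therefore be too low, and a count above it does not show an ALDH effect. Which of the calls would arise without an effect is not known. None of these 15 calls held with an estimated correlation (adjusted p from 0.797 to 0.838). The list test then has 1 residual degree of freedom and can hardly call any list, so this loss says little. Epithelial and luminal markers were the lowest in the ALDH-high fraction (mean -1.06, adjusted p = 1.67e-14 over 36 lists). At ZT0, 14 of the 18 measured members were at least 2-fold lower, with the keratins Krt18 (-4.22 and 0.02) and Krt8 (-4.07 and 0.07) and the tight junction gene Cldn3 (-4.40 and 0.34) leading; at ZT12 the list median was 0.22, inside the range of random lists (percentile 41.1). Basal and squamous markers were also lower (mean -0.53, adjusted p = 0.00114), among them Perp (-3.91 and 0.26), Krt14 (-4.70 and 1.46) and Krt6a (-0.19 and -1.96). So were Hedgehog genes (mean -0.66, adjusted p = 0.00147; Gli3 -3.31 and -0.68, Dhh -2.75 and -0.37, Smo -2.90 and -0.17) and Wnt receptors and targets (mean -0.26, adjusted p = 0.0146; Apcdd1 again, Ccnd1 -3.26 and 0.08, Fzd2 -3.07 and 0.84). Mesenchymal transition genes (mean -0.31, adjusted p = 0.00851; Mmp3 again, Tgfb3 -2.83 and 0.31, S100a4 -2.31 and 0.23) and cell cycle genes (mean -0.24, adjusted p = 0.00851; Mcm6 -2.10 and 0.71, Mcm2 -2.03 and 0.98, Foxm1 -0.90 and -0.06) had smaller shifts. Inflammatory cytokines and chemokines (mean -0.18, adjusted p = 0.0436) included Csf3 and the neutrophil attractants Cxcl5 (-1.90 and -1.41) and Cxcl1 (-1.04 and -1.79), and 3 of their 23 members were at least 2-fold lower at both times, while 14 were higher at ZT0 and lower at ZT12. Hypoxia and glycolysis genes were called down (mean -0.17, adjusted p = 0.0349; Car9 -2.90 and -0.51, P4ha2 -2.31 and -0.00, Adm -0.70 and -1.29), although their median was 0.00307 and the list ran in opposite directions: at ZT0 12 of 29 members were at least 2-fold higher and 3 lower (median 0.74), and at ZT12 15 were lower (median -1.04). The core circadian clock (mean -0.18, adjusted p = 0.0436) was led by Arntl2 (-2.56 and 0.39) and Tef (-1.73 and -0.01). That call was lost with normexp and quantile normalization (adjusted p = 0.0621), quantile normalization (0.0726), the filter on all 4 arrays (0.0698) and the series table (0.0723). The hypoxia and inflammatory calls were lost with that filter (0.101 and 0.0671). Lower too were cytosolic ribosomal proteins (mean -0.15, adjusted p = 0.0322), led by Rps2 (-1.26 and 0.53), Rpl5 (-1.32 and 0.71) and Rpl6 (-1.03 and 0.43).

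Markers of blood cells differed as well. Paired values are again ALDH-high minus ALDH-low at ZT0 and then at ZT12. Higher in the ALDH-high fraction by their mean were T and NK cell markers (0.80, adjusted p = 1.15e-05; Gzma -4.22 and 7.60, Cd3d 1.90 and 1.03, Zap70 -3.02 and 5.75), mast cell, basophil and eosinophil markers (0.70, adjusted p = 0.00486; Prss34 -0.52 and 3.72, Mcpt8 -0.47 and 3.44, Cpa3 -0.17 and 3.12), B and plasma cell markers (0.62, adjusted p = 0.0146; Ms4a1 -1.21 and 5.60, Cd22 -1.04 and 2.86) and neutrophil markers (0.45, adjusted p = 0.0400; Ly6g 4.97 and -3.06, Camp 2.51 and -0.77, Ngp 3.16 and -1.58). The neutrophil call was lost at each other scaling. Its mean was 0.26 for normexp and quantile (adjusted p = 0.169), 0.26 for quantile (0.120), 0.26 for median scaling (0.0525) and 0.25 in the series table (0.141). It was also lost without a background filter (0.172) and with no term for time (0.173). The B cell call was lost with normexp and quantile (mean 0.22, adjusted p = 0.172), without a filter (0.0552) and with no term for time (0.193). Erythroid and platelet markers were lower (mean -0.44, adjusted p = 0.00374; Car2 -3.01 and 0.93, Hbb-b2 -8.57 and 6.69, Hbb-bt -8.39 and 6.55); the globin copies are similar in sequence and uncertain as separate genes. The erythroid call was lost with normexp and quantile (0.118) and with no term for time (0.410). The marker lists with the largest differences therefore had opposite signs at the 2 times. In all 15 called lists 0 genes passed when adjusted over the list alone.

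Many of these list calls were lost or reversed when an array was left out. Each fit without 1 array compares 1 array with 2, has no term for time, and assumes that the lone array varies like the others. Its means therefore shift with the time difference within the arm that lost an array. Without the ZT0 ALDH-high array 8 lists were called, and 5 of the 15 had the opposite direction: Wnt receptors and targets (mean 0.46), basal markers (0.41), ribosomal proteins (0.36), neutrophil markers (-0.69) and erythroid markers (1.23). Neutrophil and erythroid markers also reversed without ZT0 ALDH-low (-0.54 and 1.55), where the means of Wnt receptors and targets (0.35), cell cycle (0.20) and ribosomal genes (0.15) turned positive with a downward rank and no call. Without ZT12 ALDH-low 15 lists were called and T and NK cell (-0.85), B cell (-1.22), hypoxia (0.45), inflammatory (0.55) and clock genes (-0.01 with an upward rank among genes) reversed. Without ZT12 ALDH-high, T and NK cell (-0.55), B cell (-0.65) and hypoxia genes (0.04) reversed. The Hedgehog mean moved from -0.26 without ZT0 ALDH-high to -1.06 without ZT12 ALDH-high. Its call was lost when either ZT0 array was left out. The mean of mast cell, basophil and eosinophil markers was 0.09 without ZT12 ALDH-low and 0.40 without ZT12 ALDH-high, with no call in either. The epithelial list was called in each of these fits, but its mean moved from -0.36 without ZT0 ALDH-high to -1.76 without ZT12 ALDH-high. With array position as a block, 14 lists were called, and mesenchymal (adjusted p = 0.0547), hypoxia (0.0946), inflammatory (0.152) and B cell genes (0.131) lost their call. Their means were unchanged (-0.31, -0.17, -0.18 and 0.62), since the block alters the error term alone. Within position 1_1, which compares ZT12 ALDH-high with ZT0 ALDH-low, the list medians were -0.73 for epithelial markers, 0.48 for T and NK cells, 0.53 for neutrophils and -1.01 for erythroid markers. Within position 1_2, which compares ZT0 ALDH-high with ZT12 ALDH-low, they were -1.41, 0.97, 0.40 and -0.12. Other called lists changed sign between positions 1_1 and 1_2: B cell (-0.15 and 1.19), hypoxia (0.29 and -0.41), inflammatory (0.41 and -0.62), cell cycle (-0.57 and 0.09) and ribosomal genes (0.09 and -0.39). Arm and time change together within a position. These fits by position and the list tests without 1 array were chosen after the data were seen.

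**Figure D2:**
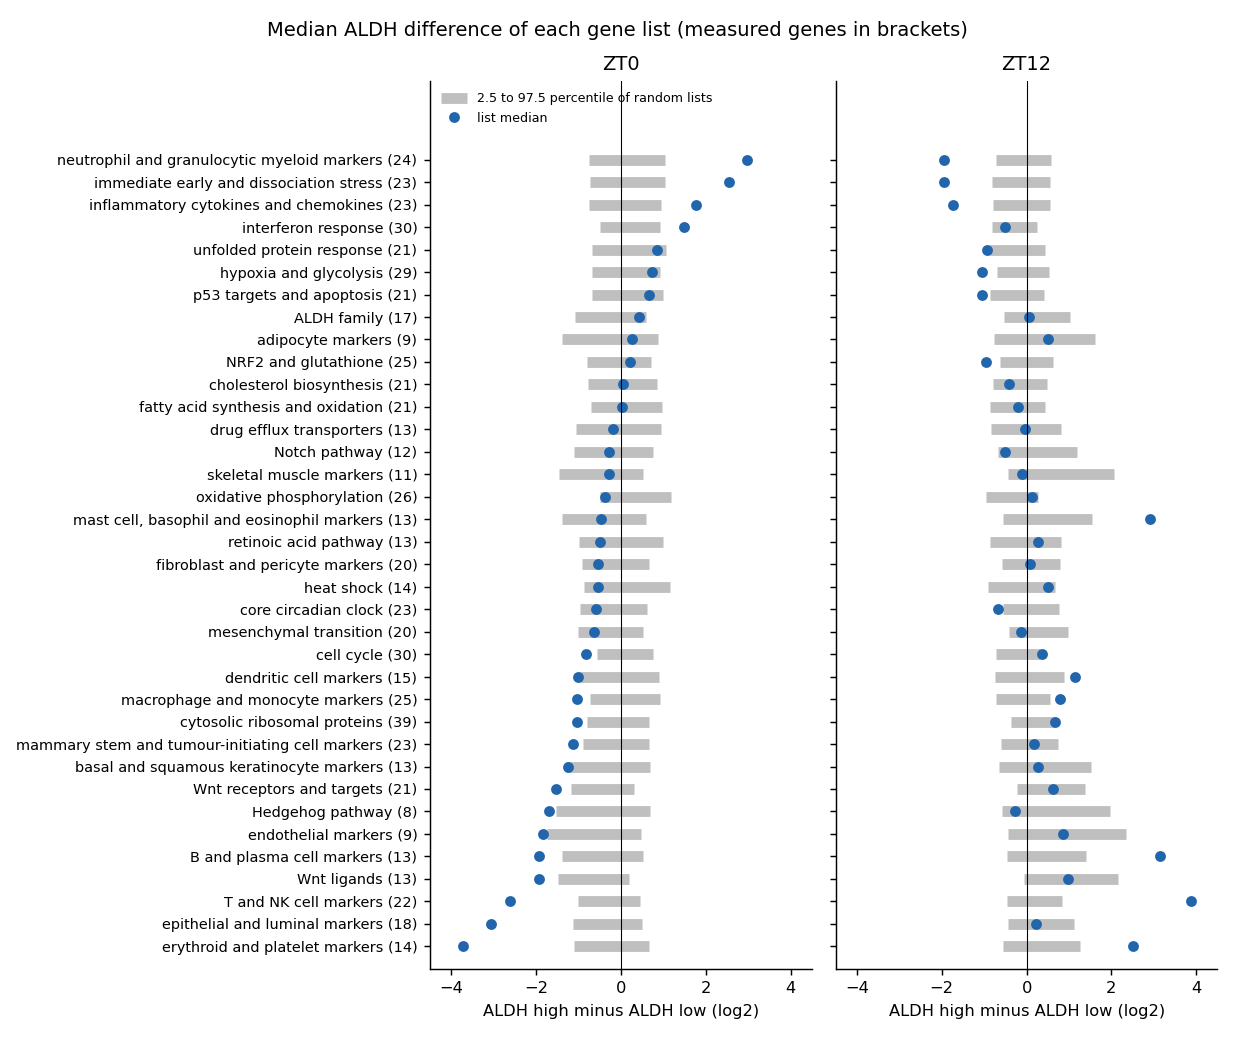
Median ALDH-high minus ALDH-low log2 difference of each of the 36 gene lists at ZT0 and at ZT12 (points), with the central range of 10000 random lists of the same size and mean level (grey bars). Neutrophil and immediate early lists lie above the range at ZT0 and below it at ZT12, and T and NK cell, B cell and erythroid lists do the reverse.

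The second comparison asked whether the ALDH difference was alike at both times. On these 4 arrays most neutrophil, inflammatory and immediate early genes were higher in the ALDH-high fraction at ZT0 and lower at ZT12. Most lymphocyte and red cell markers were the reverse, as were the medians of the dendritic and macrophage lists. The positive ZT12 median of the macrophage list depends on the scaling. The difference between times was not tested. The neutrophil list had a median of 2.97 at ZT0 and -1.96 at ZT12, with 18 of 24 members at least 2-fold higher and then at least 2-fold lower, such as the chemokine receptor Cxcr2 (4.69 and -3.18), Mmp8 (4.37 and -3.47) and Mrgpra2a (4.68 and -3.28). Immediate early and dissociation stress genes gave medians of 2.55 and -1.96, and 19 of 23 had that pattern, including Egr1 (4.13 and -3.75), Zfp36 (3.72 and -2.67), Dusp1 (3.51 and -2.78) and Klf2 (3.18 and -3.05). In the inflammatory list (1.76 and -1.74) 14 of 23 did, while 4 were lower and then higher and 3 lower at both times. Among the 14 were Nfkbiz (3.94 and -3.27), Cxcl2 (2.74 and -2.59) and Lcn2 (3.29 and -2.01). The T and NK cell list had medians of -2.61 and 3.87, with 18 of 22 members lower and then higher, such as Il2rb (-3.47 and 5.85) and Gzmb (-3.45 and 5.78). The B cell list (-1.93 and 3.14; Cd79b -4.39 and 5.62, Vpreb3 -6.90 and 6.67), the erythroid list (-3.72 and 2.505; Hba-a1 -7.85 and 6.16), the macrophage list (-1.03 and 0.79; C1qa -2.80 and 3.19, C1qb -2.57 and 3.23, C1qc -2.67 and 2.90, Aif1 -2.27 and 2.25) and the dendritic list (-1.004 and 1.14; Cd74 -1.77 and 2.76, H2-Ab1 -1.58 and 2.33) had medians of the same signs. Members at least 2-fold lower and then at least 2-fold higher were 10 of 13 in the B cell list, 8 of 14 in the erythroid list, 9 of 25 in the macrophage list, where 4 went the other way, and 7 of 15 in the dendritic list. Apart from Cd79b, which the rule for naming genes chose for time, these examples were picked after their values were seen, from the 4 members of each list with the largest such difference.

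Over all genes the ALDH difference at ZT0 and that at ZT12 were negatively correlated (Pearson r = -0.746, Spearman rho = -0.771, across 23520 genes, which are not independent replicates). The signs were opposite for 84.2% of genes. The median difference of all genes was -0.32 at ZT0 and 0.30 at ZT12, against 0.17 and -0.57 under median scaling, so single differences are relative to the scaling; the mean of both times had a median of 0.15, or -0.05 under median scaling. The correlation was negative in each other scaling and filter tried, in the series table and with the mean of a gene's probes. At this scaling 123 genes differed at least 2-fold in the same direction at both times, 39 higher and 84 lower, against 8331 in opposite directions, 3528 higher and then lower and 4803 lower and then higher. The count of 123 depends on the processing and was 11 with normexp and quantile normalization and 523 with median scaling. The largest positive values of the difference at ZT12 minus that at ZT0 were those of the globins Hbb-b2 (15.26), Hbb-bt (14.94) and Hba-a2 (14.04), and the largest negative values those of Ggt1 (-9.38), Steap4 (-9.08) and Rnf144a (-8.31). Arrays were most alike across ALDH labels: the ZT0 ALDH-low and ZT12 ALDH-high arrays correlated at 0.979 and the ZT0 ALDH-high and ZT12 ALDH-low arrays at 0.964 across genes, while every other pair lay between 0.857 and 0.877. These pairs are those of array position, which cannot be told apart from ALDH by time. The planned fit leaves no degree of freedom to test that difference.

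**Figure D3:**
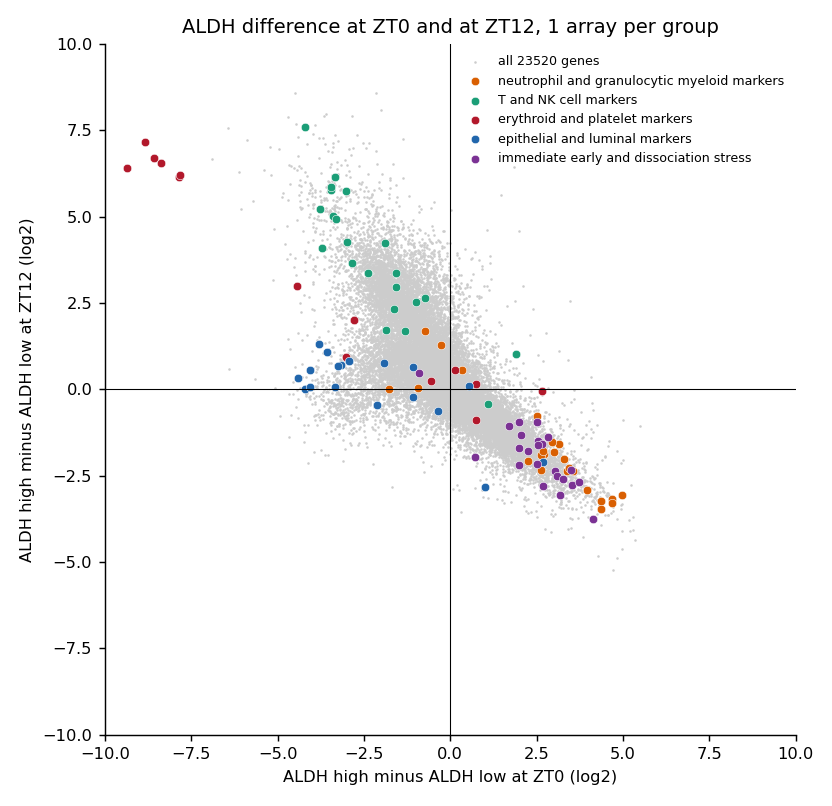
ALDH-high minus ALDH-low log2 difference at ZT0 (x axis) and at ZT12 (y axis) of 23520 genes (grey) with the members of 5 gene lists in colour. Most points run from upper left to lower right (Pearson r = -0.746), with erythroid and T and NK cell markers at the upper left and neutrophil and immediate early genes at the lower right, while most epithelial markers are low at ZT0 and near 0 at ZT12.

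The third comparison asked which transcripts differ between ZT12 and ZT0, the question of daily timing. The titles of both ZT12 samples carry an ending that the ZT0 titles lack; whether it marks a separate experiment is not given in the sources used here, so time cannot be told apart from such a difference either. Clock-controlled Dbp, a transcriptional activator that cycles in many tissues, was higher at ZT12 in both arms. Paired values here are the ZT12 minus ZT0 log2 difference in ALDH-low and then in ALDH-high cells, and Dbp gave 0.81 and 1.35. Other clock genes gave opposite signs in the 2 arms: Per1 (3.16 and -2.12), Per2 (3.13 and -1.40), Cry1 (1.78 and -0.91), Per3 (-2.07 and 1.80), Arntl, which encodes BMAL1 (-1.13 and 0.87), and Clock (-1.01 and 1.06). Nr1d1, the nuclear receptor REV-ERB alpha, gave -0.04 in ALDH-low cells and was not well above background in ALDH-high cells. Several probes disagreed in the sign of the mean difference, at 2 of 3 for Arntl, 1 of 2 for Per3, 1 of 3 for Clock and 4 of 7 for Ptprc, and the means of Per3, Arntl and Clock changed sign under other scalings or the mean of probes. As a list, the 23 measured clock genes were called up (mean 0.30, adjusted p = 0.00177), led by Ciart (3.13 and -0.80), Dbp, and Tef (0.13 and 1.84), with 0 genes passing when adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.866), where hardly any list could be called, and without each array but ZT12 ALDH-high. Only 4 genes met the rule for higher signal at ZT12 in both arms: Krt6a (3.06 and 1.29), Nars2 (2.18 and 1.06), Gpnmb (1.27 and 1.93) and Tg (1.31 and 1.74). Their levels on the ZT0 ALDH-high array were low (-3.50, -4.01, -3.86 and -3.81), where the lowest signal well above background was -4.49. Krt6a, Nars2 and Tg were also low on ZT0 ALDH-low (-3.31, -3.17 and -3.29, against -3.89). The 6 lowest were Sncb (-2.63 and -1.37), Zfp13 (-2.48 and -1.36), Adra2b (-1.33 and -2.10), Arhgef10 (-2.31 and -1.05; 1 of its 2 probes had the opposite sign), Golt1a (-1.12 and -2.15) and Igfbp5 (-1.47 and -1.34). Of the genes fixed in advance, Aldh1a1 gave -2.55 and 0.49, Aldh3a1 0.81 and -0.91, Epcam -1.80 and 2.84 and Ptprc 2.53 and -2.90. Wnt10a gave 0.50 in ALDH-low cells and was at least 7.75-fold higher at ZT12 in ALDH-high cells.

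For time, 11 lists were called, 9 up and 2 down at ZT12. In the simulated sets with no ALDH effect, camera called between 0 and 13 lists for ALDH at the same correlation. A count of 11 lies inside that range, which may be too low since its noise was independent for each gene. Time itself was not simulated. None of the 11 calls held with an estimated correlation (adjusted p from 0.866 to 0.873). That test has 1 residual degree of freedom and can hardly call any list, so the loss says little. Inflammatory genes were the furthest up (mean 0.63, adjusted p = 1.03e-10; Saa3 4.46 and -1.20, Cxcl3 2.93 and -0.31, Csf3 0.31 and 1.64), followed by basal markers (0.61, adjusted p = 1.53e-06; Krt6a, Krt14 -2.28 and 3.89, Perp -1.32 and 2.85) and hypoxia genes (0.41, adjusted p = 1.53e-06; P4ha2 -0.13 and 2.18, Adm 1.11 and 0.52, Car9 -0.45 and 1.94). Notch pathway genes (0.35, adjusted p = 0.00512) included Notch4 (0.90 and 0.30), Notch3 (1.33 and -0.22) and Notch1 (-3.16 and 4.00; 1 of its 2 probes had the opposite sign). Epithelial markers (0.29, adjusted p = 0.00487; Cldn3 -1.28 and 3.46, Krt18 -1.03 and 3.20, Gata3 -0.79 and 2.60), macrophage markers (0.26, adjusted p = 0.00268; Ms4a7 -1.02 and 2.85, Fcgr1 -0.21 and 1.87), ribosomal proteins (0.21, adjusted p = 0.00203; Rpl3 -0.76 and 1.64, Rpl4 -0.47 and 1.27, Rpl13a -0.56 and 1.33) and p53 targets (0.18, adjusted p = 0.0405; Bax -0.28 and 2.03, Perp, Bcl2l1 2.44 and -1.05) were also up. The p53 call was lost with normexp and quantile (adjusted p = 0.107), quantile (0.124), no background filter (0.0724) and the series table (0.130). The epithelial call was lost with normexp and quantile (0.0962). The Notch call was lost with the filter on all 4 arrays (0.0792). Down at ZT12 were B cell markers (-0.57, adjusted p = 0.00203; Cd79b -5.98 and 4.03, Mzb1 -3.56 and 1.81) and heat shock genes (-0.50, adjusted p = 0.00512), with Hspa1b (-1.43 and -1.38) and Hspa1a (-1.27 and -1.29) lower in both arms and Hspb1 (-3.28 and 1.49) in one. The B cell call was lost with normexp and quantile (0.133) and with no term for ALDH arm (0.166).

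The time test called 0 genes in limma (2 at an unadjusted p under 0.05, standard error 1.54 log2 units). The time difference in the ALDH-low arm and that in the ALDH-high arm were negatively correlated across genes (Pearson r = -0.835, Spearman rho = -0.858), and 64 genes differed at least 2-fold in the same direction against 9173 in opposite directions. The heat shock list kept its sign but lost its call whichever array was left out. Its mean ranged from -0.20 without ZT12 ALDH-low to -0.79 without ZT12 ALDH-high. Without the ZT0 ALDH-high array the epithelial (mean -0.80), basal (-0.29) and ribosomal lists (-0.26) reversed, and the mean of macrophage markers turned to -0.06 with an upward rank. Without ZT0 ALDH-low, p53 targets (-0.15) and B cell markers (0.68) reversed, and without ZT12 ALDH-low, 6 lists were called and hypoxia (-0.09), p53 (-0.29) and B cell markers (1.30) reversed, as did inflammatory genes in rank (0.13). Without ZT12 ALDH-high the means of ribosomal (-0.12) and macrophage genes (-0.13) turned negative with an upward rank and no call. That fit called 1 gene lower, Gzmc (limma adjusted p = 0.0439), named after its values were seen. No fold is given for it, since its level on the 1 remaining ZT12 array (-5.03) is under the lowest signal well above background there (-4.93), and its levels on the ZT0 arrays were 3.59 and -0.90. With position as a block the epithelial list lost its call (adjusted p = 0.0559) at the same mean of 0.29.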

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

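Of the tests named here, those on pairs of probes, exchanged labels, the mix of cells and a mesenchymal shift were chosen after the result was seen. The fixed rule for naming genes was written earlier, but many of the immune cell, immediate early, inflammatory, interferon and ribosomal genes here were picked after their values were seen, from the members of 10 lists with the largest such values. A gene is listed where its ALDH-high minus ALDH-low difference was at least 2-fold in one direction at ZT0 and at least 2-fold in the other at ZT12, and a list where its medians lay outside the range of random lists on opposite sides. With 1 array per combination none of these differences between times was tested.

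Of 138 named genes measured on all 4 arrays, 61 had such values, 35 of them positive and 26 negative. The values are the log2 ALDH difference at ZT12 minus that at ZT0. Globin genes came first, with 15.26 for Hbb-b2, 14.94 for Hbb-bt, 14.04 for Hba-a2 and 14.02 for Hba-a1. Among lymphocyte genes the values were 13.57 for Vpreb3, 11.82 for Gzma, 10.01 for Cd79b, 9.32 for Il2rb, 9.23 for Gzmb, 8.77 for Zap70, 6.81 for Ms4a1, 5.37 for Mzb1 and 3.90 for Cd22. Among macrophage and antigen presentation genes they were 5.99 for C1qa, 5.80 for C1qb, 5.57 for C1qc, 4.53 for Cd74, 4.52 for Aif1, 3.91 for H2-Ab1, 3.87 for Ms4a7, 3.84 for H2-Aa and 3.70 for H2-Eb1. Other positive values were 7.16 for Notch1, 6.17 for Krt14, 4.76 for Hspb1, 4.65 for Epcam, 4.39 for Aldh1l2, 3.87 for Per3, 3.25 for Aldh1l1, 3.03 for Aldh1a1, 2.82 for Rpl14, 2.77 for Rpl10a, 2.49 for Rps18, 2.47 for Rpl32 and 2.31 for Bax.

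Negative values were led by Ggt1 (-9.38), Steap4 (-9.08) and Rnf144a (-8.31). Neutrophil genes gave -8.03 for Ly6g, -7.96 for Mrgpra2a, -7.88 for Cxcr2, -7.84 for Mmp8, -5.31 for Lcn2 and -4.74 for Ngp. Immediate early genes gave -7.88 for Egr1, -6.38 for Zfp36, -6.29 for Dusp1 and -6.23 for Klf2, and inflammatory genes -7.21 for Nfkbiz, -5.66 for Saa3, -5.33 for Cxcl2 and -3.24 for Cxcl3. Interferon genes gave -5.59 for Oas2, -4.56 for Ddx58, -3.95 for Oasl1 and -3.69 for Gbp2. Clock genes gave -5.28 for Per1, -4.53 for Per2 and -3.93 for Ciart. The others were Ptprc (-5.43) and Bcl2l1 (-3.49). Of the 36 lists, 10 had medians on opposite sides, 3 of them higher in ALDH-high cells at ZT0: neutrophil (2.97 at ZT0 and -1.96 at ZT12), immediate early (2.55 and -1.96) and inflammatory genes (1.76 and -1.74). The 7 with lower medians at ZT0 were erythroid (-3.72 and 2.505), T and NK cell (-2.61 and 3.87), B cell (-1.93 and 3.14), ribosomal (-1.03 and 0.68), macrophage (-1.03 and 0.79), dendritic (-1.004 and 1.14) and cell cycle genes (-0.82 and 0.35). Median scaling moved the ZT12 median of all genes from 0.30 to -0.57. The ZT12 medians of the ribosomal, macrophage and cell cycle lists would turn negative under it. Median scaling shifts all genes alike, so for these lists only the place among random lists would still reverse. That place was not computed under the other scalings.

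For these opposite differences, 2 technical explanations met values against them. After smooth trends on signal level and probe GC content were removed, the correlation of the 2 ALDH differences across genes was -0.722, which argues against these trends, as from a dim hybridisation, as the whole source. Noise of single probes was argued against by pairs of probes of one gene, whose position contrasts correlated at 0.667 over 6751 genes. Exchanged labels of one pair of sorted fractions, either at ZT0 or at ZT12, cannot be told apart from a real reversal. The smallest gap by which each array was closer to the other label at the other time, 0.0873 in correlation, restates the pairing already seen and decides nothing. A different mix of neutrophils, lymphocytes and red cells in the fractions also stays open. The count of list medians on the side it names, 8 of 8, restates the medians that prompted it and lends it no support. Against a simple change in neutrophil number, S100a8 and S100a9, abundant neutrophil transcripts in the same list, differed by 0.35 and -0.26 at ZT0. At ZT12 they differed by 0.57 and 1.27. The list median was 2.97 at ZT0 and -1.96 at ZT12. The levels of S100a8 and S100a9 were among the highest on every array, and whether signal is compressed there was not tested. Other members with high levels differed with the list: Camp by 2.51 and -0.77, Ngp by 3.16 and -1.58 and Lcn2 by 3.29 and -2.01, so the list's abundant members do not settle it. An ALDEFLUOR gate alone would not remove blood cells, and whether another gate did is not given in the sources used here. Of the lists used, 1 neutrophil gene and 1 T and NK cell gene are also held by another list; how many the tumour cells themselves express is not known from these arrays. The array position, which is the same contrast, and a biological effect of time on the ALDH fractions stay open and untested.

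The low epithelial markers on the ZT0 ALDH-high array, with a list median of -3.05 at ZT0 against 0.22 at ZT12, were weighed as a second pattern. Signal level and GC content met a value against them as the whole source, since the median stayed at -2.57 after their trends were removed. Fewer tumour epithelial cells in that fraction may contribute. Of 47 other keratin, claudin and adhesion genes outside the lists, 74.5% (35 genes, median -1.16) were lower at ZT0, between the bounds set before the test. At ZT12, 21 were lower (median 0.40). The median of all genes at ZT0 was itself -0.32 at this scaling and 0.17 under median scaling. The 74.5% therefore depends in part on the scaling. For a mesenchymal shift of the tumour cells no value spoke in favour. The mesenchymal list had a median of -0.63 at ZT0, at percentile 22.28 of random lists. There 9 members were at least 2-fold lower and 4 higher. Camera called the list down for ALDH at the preset correlation (mean -0.31, adjusted p = 0.00851). The call was lost with position as a block (adjusted p = 0.0547) and without 3 of the 4 arrays. It was also lost at the estimated correlation (0.797), where hardly any list could be called. A mesenchymal shift was not excluded, since the ZT0 median lies inside the random range. The bound against it was first set at the 50th percentile, which this value would have met. It was moved to the 2.5th after the value was seen, because a median inside the random range decides nothing. A biological difference between ALDH fractions stays open.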

How the results depend on the processing

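The fits by array position and the list tests without 1 array were chosen after seeing the data. The other alternatives were planned. In all of them limma called 0 genes for ALDH; for time it called 0 genes in each but the fit without ZT12 ALDH-high, which called 1, Gzmc (range without 1 array 0 to 1), a gene not well above background on the 1 ZT12 array left.

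With an estimated inter-gene correlation 0 lists were called for ALDH and 0 for time. The list test then has 1 residual degree of freedom and can hardly call any list, so this says little. With a correlation of 0.05, 6 lists were called for ALDH against 15, and 10 for time against 11. Without 1 array the number of lists ranged from 8 to 15 for ALDH and from 6 to 14 for time. No called list reversed under another scaling, filter or probe choice, but lists reversed when an array was left out, 5 for ALDH without ZT0 ALDH-high and 5 without ZT12 ALDH-low. With no term for time, these ALDH means shift with the time difference within the arm that lost an array. The reversed means follow from that shift and do not by themselves mark an array as deviant. The ALDH call of the neutrophil list was lost in 8 of 15 settings and reversed in 2 more. That of the epithelial list was lost only with the estimated correlation; its time call was lost in 5 of 15 settings and reversed in 1.

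The 123 genes at least 2-fold in the same direction at both times became 11 with normexp and quantile normalization, 260 with quantile normalization, 523 with median scaling, 49 with the background filter on all 4 arrays (fewer genes tested), 446 without the filter (more genes tested) and 273 in the series table. Opposite directions stayed the more frequent, from 4173 to 11424 genes. Median scaling moved all ALDH differences at a time by the same amount and left the Spearman rho at -0.771, so its count follows from that shift. Apart from this and the filters, the cause was not tested.

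Of 996 planned tests of 125 named results, 983 kept direction and 13 reversed, with none past the threshold (lowest adjusted p rounding to 1). Many of these could not reverse. Leaving out the other factor keeps the mean difference in this balanced design, and the filters mostly keep the same probe. The series table is itself quantile normalized, so it nearly repeats that setting. The reversed mean differences for time were Per3 (0.0639) and Clock (-0.0611) with normexp and quantile, Clock with quantile (-0.0184) and in the series table (-0.0194), Aldh3a1 (0.0953), Arntl (0.0176) and Per3 (0.0128) with median scaling, and Arntl (0.335), Per3 (0.152) and Ptprc (0.139) with the mean of probes. For ALDH they were Aldh3a1 (-0.0138) and Per2 (-0.0634) with median scaling and Per3 (-0.0885) with the mean of probes. Median scaling moves the mean difference of every gene in a comparison by the same amount, so its reversals are of means near 0. The cause of the others was not tested. Genes near background are limited by the signal of the dimmest array, where 55.8% of spots were well above it.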

Other observations

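Every test of probes outside curated transcripts was set before its result was seen; the genes whose levels are given were picked after their values were seen. Interferon response genes had a median ALDH difference of 1.49 at ZT0, at percentile 99.98 of random lists, and -0.51 at ZT12, and were not called (adjusted p = 0.067). Mammary stem and tumour-initiating cell markers had medians of -1.13 and 0.18 (adjusted p = 0.0891) and endothelial markers -1.83 and 0.86 (adjusted p = 0.713). For ALDH the other lists without a call were immediate early (adjusted p = 0.331), Notch (0.0634), retinoic acid (0.531), NRF2 and glutathione (0.178), drug efflux (0.178), oxidative phosphorylation (0.067), cholesterol (0.119), fatty acid (0.249), heat shock (0.531), unfolded protein response (0.640), p53 (0.0891), macrophage (0.664), dendritic (0.635), fibroblast (0.0576), adipocyte (0.277) and skeletal muscle genes (0.692). The median, mean and test direction differed in sign in 9 lists for ALDH (ALDH family, Wnt ligands, retinoic acid, hypoxia, NRF2, unfolded protein response, macrophage, endothelial, skeletal muscle) and in 6 for time (Wnt receptors, NRF2, drug efflux, immediate early, neutrophil, adipocyte).

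Levels of 4 transcripts are given for each array, and levels of different probes do not share a scale. On ZT0 ALDH-low, ZT0 ALDH-high, ZT12 ALDH-low and ZT12 ALDH-high the normalised levels were 8.60, 8.95, 8.65 and 9.22 for S100a8, 9.97, 9.71, 9.23 and 10.50 for S100a9, 9.19, 9.34, 8.74 and 9.33 for Lyz2, and 5.68, 1.61, 4.28 and 4.36 for Krt8.

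Relative to probes of named genes, probes outside curated transcripts were higher on the pair of dim arrays, those of position 1_1. The median position contrast was 0.71 for 2551 lincRNA probes and 0.03 for 25031 probes of named genes. Median scaling would move both values by the same amount, so only the gap between them is read. A change of the gene itself as the whole source was argued against within 3254 genes. There the probe of another accession stood above the RefSeq probe by a median of 0.379 and in 65.5% of genes. These probes were not matched on level, and the contrast fell with level across genes (Pearson r = -0.310), so level may contribute to that gap. Signal level as the whole source was argued against for lincRNA probes alone, by a gap of 0.428 at matched level. What set these probes apart stays open, and unspliced or genomic nucleic acid was not tested.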
